A study of Caenorhabditis elegans with 53 samples.

How the data were processed

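RNA from nuclei of Caenorhabditis elegans was sequenced in 53 libraries that fall into 12 groups. Per the labels, a strain carried a nuclear tag in neurons (the INTACT method), animals were grown in synchrony and collected a set time after plating, and tagged neuronal nuclei were pulled down from a preparation of nuclei. These libraries are called neuronal IP here, and libraries from the whole preparation are called input. Per the submitters' processing notes, reads were aligned with Subread, assigned to genes with featureCounts and compared with DESeq2; versions were not given. Genome build and the strandedness of counting are not given in the sources used here, so reads of a gene that overlaps another cannot be assigned to a strand.

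The deposited table of raw counts holds counts per gene for the 38 control libraries, with 41897 genes of which 7615 were at 0 in every library. The deposited size-adjusted table is treated as a score: in it the authors rescaled the counts of each of 37 neuronal IP libraries to a common sum over 7974 genes and rounded them, since library sums were between 3998798 and 4000500 and 100% of the control values equalled the rescaled raw counts after rounding (tolerance 0.501). A pair of deposited normalized tables, one for development and one for the mutants, holds a signal, namely the size-adjusted values divided by factors. The authors' gene table holds other values, gene lengths and coordinates, of which 78.9% of lengths were multiples of 3.

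In the deposited normalized tables the factor of a value did not follow its library. Over 885 genes with all values of at least 500, 4.55% of the developmental values carried the factor of their own library, and 22 factors occurred in 22 patterns that changed from gene to gene. Over 843 genes of the mutant table, 0.34% of values carried the factor of their own library. For this reason the mutant comparisons used the size-adjusted values of 6148 genes divided by a median-ratio factor computed for each of 26 libraries (0.68 to 1.46), a choice made after the data were examined; the size-adjusted and the deposited values were kept as alternatives. The mean of these factors was 1.2 in L1 control, 0.885 in adult control, 1.04 in adult lin-4 null, 1.14 in lin-14 gain of function, 0.814 in lin-28 gain of function and 1.15 in L1 lin-4 null libraries.

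Of the identifiers, 40659 matched the gene table, as did 7724 of the 7974 genes of the authors' set. The matched genes lay on 6 chromosomes, with 0 genes of the mitochondrial genome, and 11 gene names had been turned into dates in the tables. Each of the 53 libraries had a column in the tables that could be mapped to its label.

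Control libraries were compared with edgeR 4.0.16 (quasi-likelihood, TMM scaling, genes kept by filterByExpr with a minimum count of 10) and mutant libraries with limma 3.58.1 (trend and robust variance, log2 of the value plus a pseudocount of 1, genes with at least 10 in 3 libraries), in R 4.3.3. Adjusted p is the Benjamini-Hochberg value over all genes of a comparison, and genes with adjusted p under 0.05 are called higher or lower. Log2 fold changes carry the standard error (SE) of the model, and levels are means of normalized counts with the SD over libraries. The labels do not say that replicates were separate cultures, so p-values measure the spread between these samples, which may be technical. DESeq2 1.42.0, median-ratio (RLE) scaling in edgeR, no filter on low counts, pseudocounts of 0.5 and 10, each comparison fitted on its own groups, the stage genes of the edgeR comparison for the overlap with mutants, and leaving out each library were alternatives fixed before the data were examined, as were the groups, comparisons, gene lists and the rule for named genes. Chosen after the data were examined were scaling on the genes higher in neuronal IP than input, adult libraries 1 to 3 or 4 to 7 alone, L4 libraries 1 to 3 or 4 to 6 alone, a fit of L1 libraries alone with the replicate block, and the stage genes of the edgeR comparison scaled on neuron-enriched genes for the overlap with mutants. The overlap of stage and mutant changes was planned as a number of genes; under the alternatives it is given as a percent of the stage genes. That change was made after the data were examined, because 2 of the numbers coincide with digits of gene names in the fixed design and could not be printed, and it altered which alternatives count as having moved the overlap in 4 cases.

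A gene is called neuron-enriched where it was higher in neuronal IP than in input over all stages; 8632 genes were. Of the authors' 7974 genes, 7157 passed the filter here and 7145 of these were neuron-enriched. The authors' set was chosen on these samples, so its direction against input is not independent evidence.

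The 24 gene lists were compiled from gene symbols and general knowledge of the worm, and not from a database: pan-neuronal genes, neurotransmitter synthesis and transport, neuropeptides, chemoreceptor-type GPCRs, guanylyl cyclases, ionotropic receptors, potassium channels, innexins, adhesion and guidance, homeobox transcription factors, the heterochronic pathway, ciliary transport, ribosomal proteins, cell division, heat shock, body wall muscle, pharyngeal muscle, intestine, hypodermis and cuticle, germline and oocyte, sperm, glia, coelomocyte and vulval or uterine markers, and the mitochondrial genome. The guanylyl cyclase list was made for receptor cyclases by symbol and also holds soluble ones such as gcy-35 and gcy-36. Lists of at least 5 genes were tested with camera at a preset correlation of 0.01 and with an estimated correlation; with the estimate, 0 lists were called in each of the 16 comparisons tested.

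Named genes are lin-4, lin-14 and lin-28 in mutant comparisons, the called genes with the highest and lowest log2 fold changes (at most 6 each way, 3 for consecutive stages) among those with a mean of at least 50, full separation of the groups' libraries and, between stages or genotypes, neuron enrichment, and at most 4 called members of each list by adjusted p. In these genes of the highest and lowest fold change, every library of the higher group was above every library of the other group. Genes without a symbol were skipped in this rule.

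Whether replicate numbers pair samples was checked by the correlation of same-numbered libraries' deviations from their group means. They did pair neuronal IP and input at L1 (0.16 to 0.29), L4 (0.23 to 0.48) and adult (0.36 to 0.69) and the L1 lin-4 null and L1 control libraries (0.19 to 0.44), and did not at L2 (lowest 0.08), between stages or for the adult mutants. The pairing comes from the data and not from the labels. No control library was a copy of another of its group: over 77 pairs the lowest overdispersion ratio was 5.15. Mutant libraries, without raw counts here, were not checked in this way.

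Total counts of the control libraries ranged from 8582120 to 53251753, and counts in the authors' gene set from 2758827 to 10934263 in the neuronal IP. For 14 of the 15 mutant libraries the factor of the rescaling, which gives the depth in that set, was estimated from the rounding of the values at 0.322 to 0.809; the same estimate was within 1 percent for 18 of 18 control libraries where it could be made. The pipeline was tested on simulated data with known changes: with the stage groups' sizes, 4-fold changes were called for 70.3% of genes between L1 and L2 and 80.3% between L1 and adult, and with the mutants' sizes for 93.4% in adult lin-4 null, 90.9% in L1 lin-4 null, 98.6% in lin-14 and 98.3% in lin-28 libraries. Few genes were changed in each simulation, which makes the adjusted p stricter there than in comparisons with many calls.

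Overlaps between comparisons that share adult controls were set beside 100 simulations of the shared error without any change and beside a fit in which the adult controls were split between the comparisons. Labels were reassigned among the libraries of each comparison, with the draw fixed by seed 20. Isoforms, single cells and mature microRNAs were not analysed here.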

Results

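Nuclear RNA was measured in neurons of the nematode at 4 stages, together with the RNA of all nuclei of the same preparations. The control neuronal IP comprised 4 L1 libraries (8 ± 1 h after plating), 5 L2 (21 ± 1 h), 6 L4 (40 ± 2 h) and 7 adult libraries (53 ± 2 h), and the inputs 4, 3, 4 and 5 libraries. Neuronal IP libraries of heterochronic mutants, in which the timing of larval events is altered, comprised 3 L1 and 4 adult libraries of a lin-4 null, 5 adult libraries of a lin-14 gain of function and 3 adult libraries of a lin-28 gain of function. Adult lin-4 and lin-14 mutants were collected at 57 ± 2 h, since the labels state that they grow more slowly. Total counts per library ranged from 8582120 to 18122090 in L1, 14003066 to 24838138 in L2, 9816934 to 27363082 in L4 and 14467748 to 53251753 in adult neuronal IP. In the inputs they ranged from 13396137 to 32095619, 15610163 to 30335984, 9960845 to 14838870 and 18826405 to 41927678 by stage. The genes of the authors' neuronal set took 50.3 ± 2.3% of the counts in L1 neuronal IP, 42.5 ± 8.6% in L2, 33.4 ± 9.2% in L4 and 26.8 ± 5.8% in adult, against 17.7 ± 1.2%, 15 ± 1.6%, 11.2 ± 0.5% and 9.3 ± 2.0% in the inputs.

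The comparison of neuronal IP with input asks which transcripts the pull-down of neuronal nuclei enriches. Genes of neuronal signalling stood far above the input. The neuropeptide gene flp-18 averaged 6510 ± 3679 normalized counts (SD, n = 22) in neuronal IP and 376 ± 291 (n = 16) in input, a log2 fold change of 4.28 (SE 0.25, edgeR adjusted p = 5.28e-17). The genes of a pair of NMDA-type glutamate receptor subunits, nmr-2 and nmr-1, had log2 fold changes of 4.2 (SE 0.22) and 4.13 (SE 0.24), and cwp-5 had 4.15 (SE 0.28). The intestinal proton pump subunit gene vha-6 lay below the input and fell by 1.5 (SE 0.16, from 13040 ± 4887 to 4944 ± 2342). The germline helicase gene glh-2 fell by 1.36 (SE 0.17) and the replicative helicase gene mcm-6 fell by 1.15 (SE 0.14). Among genes of the lowest fold change named by the rule, hpo-8 fell by 1.22 (SE 0.09) and the mitochondrial ribosomal protein gene mrps-9 fell by 0.50 (SE 0.06).

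By gene group, 22 of 22 pan-neuronal genes were higher in neuronal IP, with a median log2 fold change of 2.86. They included unc-104, the kinesin that carries synaptic vesicle precursors (3.33, SE 0.18), the Ras exchange factor gene rgef-1 (3.65, SE 0.20) and the SNAP-25 gene ric-4 (3.31, SE 0.18). Of 18 genes of neurotransmitter synthesis and transport, 15 were higher and 2 lower (median 3.12), among them the choline acetyltransferase gene cha-1 (4.01, SE 0.19), the vesicular acetylcholine transporter gene unc-17 (3.76, SE 0.19) and the vesicular glutamate transporter gene eat-4 (3.70, SE 0.19). Of 121 neuropeptide genes, 96 were higher and 9 lower (median 3.05), such as flp-11 (3.44, SE 0.15) and nlp-11 (3.72, SE 0.19). Chemoreceptor-type GPCRs were higher for 823 of 869 genes and lower for 9, or 830 and 10 when adjusted over the list alone, with a median of 3.33. Guanylyl cyclases, which act in sensory neurons, were higher for 33 of 34 and lower for 0 (34 higher when adjusted over the list alone), for example daf-11 (3.80, SE 0.18), and ciliary transport genes for 40 of 40. The ionotropic receptors had 85 higher, 6 lower and 12 not called, with the glutamate receptor subunit gene glr-5 at 3.91 (SE 0.17), and potassium channels had 51 and 10 of 71. The adhesion and guidance genes had 51 higher and 8 lower of 64, homeobox genes 66 and 11 of 91 (69 and 11 when adjusted over the list alone) and the heterochronic pathway 15 and 3 of 22, with lin-14 at 1.60 (SE 0.12).

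Other lists went the opposite way or were mixed. Ribosomal protein genes were lower for 71 of 80 and higher for 1, cell division genes lower for 28 of 32, germline and oocyte markers for 35 of 38, intestine markers for 19 of 25 and body wall muscle markers for 14 of 18, with 0 higher in these last 4 lists. Innexins had 8 higher and 10 lower of 25, with the neuronal innexin genes unc-7 (3.33, SE 0.17) and inx-19 (3.27, SE 0.17) among the higher; their median was -0.14 and their mean 0.31. Hypodermis and cuticle markers had 27 higher and 17 lower of 210, sperm markers 7 and 4 of 78, coelomocyte and vulval or uterine markers 4 and 5 of 10, heat shock genes 2 and 3 of 11, and pharyngeal muscle markers 2 and 0 of 8. Glia markers had 4 higher and 2 lower of 17, with a median of 0.01 that turned to -0.17 with RLE scaling; the set test had the sign opposite to the median for glia, pharyngeal muscle and sperm markers. The mitochondrial genome list had 0 genes in the tables. In the list tests 16 lists were called with the preset correlation, and the lowest adjusted p with an estimated correlation was 0.152.

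**Figure D1:**
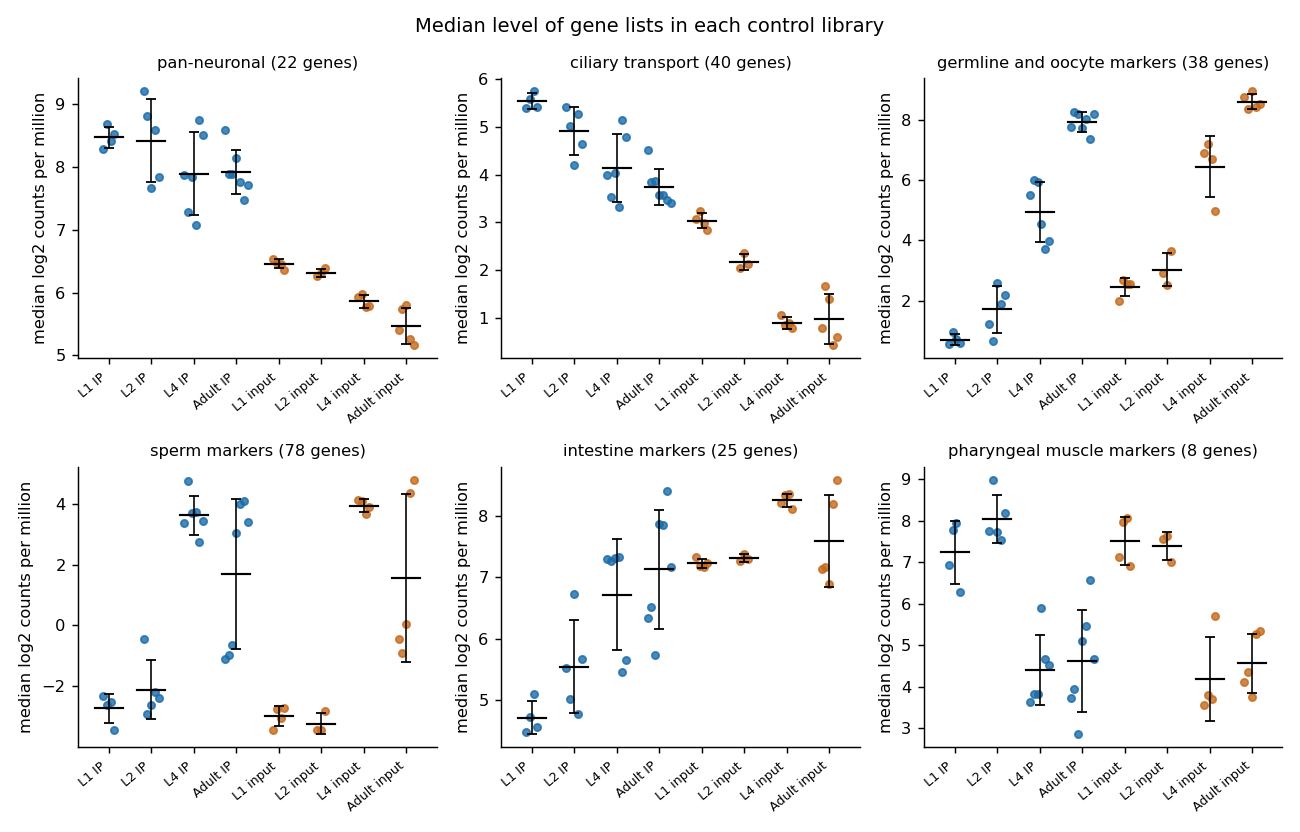
Median log2 CPM of 6 gene lists in each control library (points), with the mean and SD of each group (lines), for neuronal IP and input at each stage. From L1 to adult the germline and oocyte list moved by 6.69 in neuronal IP and 5.85 in input.

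Over 21040 genes, 8632 were higher and 4926 lower in neuronal IP (edgeR, Benjamini-Hochberg). The balance was 7698 and 6340 with RLE scaling, 8416 and 8013 without the filter on low counts and 8166 and 6872 with the replicate block. With RLE scaling the median of all genes fell by 0.18 on the log2 scale in the comparison over stages, by 0.30 at L2 and by 0.22 in adults. By stage, 7152 genes were higher and 3721 lower at L1, 6545 and 2360 at L2 (5191 and 3939 with RLE scaling), 6082 and 2711 at L4, and 5441 and 2511 in adults (4931 and 4669 with RLE scaling). Without the filter on low counts the balance was 5307 and 5923 at L1, 3958 and 4959 at L2, 4698 and 4621 at L4, and 5177 and 2497 in adults. The adult replicate numbers pair neuronal IP and input, and a fit with the replicate block called 12011 genes there, 5292 higher and 6719 lower. The median log2 fold change of the neuron-enriched genes was 2.17 at L1, 2.15 at L2, 2.48 at L4 and 1.99 in adults.

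The difference between these stage changes asks whether the contrast of neuronal IP with input moved from L1 to adult. It moved higher for 48 of 121 neuropeptide genes and lower for 1 (57 and 1 when adjusted over the list alone; median 1.58). In this list flp-26 had a log2 difference of 2.60 (SE 0.51, edgeR adjusted p = 0.00163). Ionotropic receptors had 36 higher, 1 lower and 66 not called, potassium channels 25 higher and 0 lower of 71, and intestine markers 10 and 0 of 25. The medians of these lists were 1.25, 1.18 and 1.47. Lists of other tissues had like medians, at 1.30 for hypodermis and cuticle, 1.21 for glia, 0.96 for body wall muscle and 0.93 for germline and oocyte markers. The median was 0.42 for chemoreceptor-type GPCRs, -0.91 for sperm markers and -0.01 over the neuron-enriched genes, so the move is not particular to neuronal lists. Single libraries stood apart in some of these lists: L1 neuronal IP replicate 1 was low for neuropeptides (median log2 CPM 4.50, others 5.73 to 5.92), L1 neuronal IP replicate 4 was high for ionotropic receptors (4.66, others 4.42 to 4.46), and for potassium channels adult neuronal IP replicate 1 was high (5.03, others 4.12 to 4.41) and adult input replicate 1 low (1.54, others 1.70 to 1.75). The SNAP-25 gene ric-4 moved by 1.99 (SE 0.43) and the innexin gene unc-9 by 1.89 (SE 0.40). The octopamine synthesis gene tbh-1 went the other way (-3.36, SE 0.55), as did the tyramine synthesis gene tdc-1 (-2.37, SE 0.48) and lin-41, a TRIM-NHL factor of the heterochronic pathway (-1.83, SE 0.42). In all, 1751 genes were called higher and 1639 lower (1348 and 2162 with RLE scaling, 3673 and 459 without the filter on low counts), and the fit with the replicate block, at stages whose numbers pair the samples, called 6167 (3188 higher and 2979 lower). A fit of the 4 groups compared alone called 7110.

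The comparisons between stages of the neuronal IP ask which transcripts differ in tagged neuronal nuclei from the youngest larva to the adult. They do not tell change within neurons from a change in which neurons are present. Between L1 and L2 genes of the heterochronic pathway were among those called. The gene of the microRNA mir-241 rose from 3.52 ± 3.62 (n = 4) to 101 ± 106 normalized counts (n = 5), a log2 fold change of 4.71 (SE 0.79, edgeR adjusted p = 0.00204). The gene mab-10, a transcription cofactor, rose by 3.51 (SE 0.49, from 50.7 ± 38.6 to 566 ± 343), and lin-42, the worm relative of period, rose by 3.43 (SE 0.53). The RNA-binding protein gene lin-28 (chromosome I, 8408155 to 8410797) fell by 1.48 (SE 0.21, from 1258 ± 245 to 451 ± 56; adjusted p = 0.000581). Counts assigned to a microRNA gene do not measure the mature microRNA. Of the 22 heterochronic genes, 7 rose, 1 fell and 14 were not called (9 rose and 1 fell when adjusted over the list alone). The zinc finger gene bnc-1 rose by 4.36 (SE 0.72), the insulin-like gene ins-9 by 3.17 (SE 0.50), the immunoglobulin-domain gene zig-2 by 2.34 (SE 0.47) and the Hox gene ceh-13 by 1.34 (SE 0.27).

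Of 202 hypodermis and cuticle markers 45 were higher, 0 lower and 157 not called, with the collagen gene col-90 at 5.83 (SE 0.69). With scaling on neuron-enriched genes 1 of 27 was higher. Germline markers had 6 higher and 0 lower of 38. Chemoreceptor-type GPCRs had 12 lower and 2 higher of 785 (median -0.77), guanylyl cyclases 4 lower and 0 higher of 34, and 0 of 22 pan-neuronal and 0 of 40 ciliary transport genes were called, with edgeR in each case. With scaling on neuron-enriched genes the chemoreceptor list had 9 lower and 2 higher of 756 (median -0.48) and the guanylyl cyclases 1 lower and 0 higher of 33. Over 19658 genes 474 were higher and 79 lower in L2. DESeq2 called 1393 genes and a fit of the L1 and L2 libraries alone 1357. Of the neuron-enriched genes 113 were called (44 higher and 69 lower), and 144 (109 higher and 35 lower) when scaling and testing used the 8267 neuron-enriched genes alone. Without L1 replicate 1, 2, 3 or 4 the count was 257, 158, 155 or 367, and without L2 replicate 3 or 5 it was 269 or 302.

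From L2 to L4, lin-41 fell by 2.50 (SE 0.25, from 7955 ± 1843, n = 5, to 1404 ± 192, n = 6; edgeR adjusted p = 1.17e-06), while mab-10 rose by 3.49 (SE 0.43) to 6361 ± 1861 and lin-42 rose by 2.25 (SE 0.45) to 28280 ± 13390. Of the 18 neurotransmitter genes 5 were lower and 13 not called. The lower ones included the GABA transporter gene snf-11 (-1.45, SE 0.20), the vesicular GABA transporter gene unc-47 (-1.1, SE 0.25) and the GABA synthesis gene unc-25 (-1.07, SE 0.29). The neuropeptide gene flp-1 fell by 1.28 (SE 0.20, from 7639 ± 1121 to 3139 ± 698), and the Slit ligand gene slt-1 fell by 1.60 (SE 0.19). The soluble guanylyl cyclase gene gcy-36 fell by 1.16 (SE 0.22) and gcy-35 fell by 1.28 (SE 0.30). Each of these calls was also made with scaling on neuron-enriched genes, where flp-1 was at -0.94 and slt-1 at -1.29, except for lin-41 and lin-42, which are not among those genes.

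By list, guanylyl cyclases had 12 lower and 0 higher of 34 (7 lower of 33 with scaling on neuron-enriched genes), homeobox genes 25 lower and 4 higher of 88 (5 and 2 of 66), and neurotransmitter genes 5 lower and 0 higher of 18 (5 and 0 of 15). Neuropeptides had 10 lower and 7 higher of 116, with a median of -0.13 that turned to 0.15 with scaling on neuron-enriched genes, and heterochronic genes 8 lower and 3 higher of 22, with a median of -0.20 that turned to 0.30. Markers of other tissues moved in the same libraries. Of 77 sperm markers 75 rose and 0 fell (median 6.57; 7 of these genes were neuron-enriched), with the sperm ferlin gene fer-1 at 3.80 (SE 0.37). Germline and oocyte markers rose for 37 of 38 (median 3.37), such as the synaptonemal gene syp-1 (3.55, SE 0.38), and cell division genes for 27 of 32, such as the cyclin gene cyb-1 (4.03, SE 0.50). The collagen genes bli-2 and col-175 rose by 10.00 (SE 0.89) and 7.92 (SE 1.15), the yolk gene vit-2 rose by 4.79 (SE 0.79), and 8 of 8 pharyngeal muscle markers fell, including the myosin gene myo-5 (by 3.66, SE 0.55). In all 3632 genes were higher and 1435 lower in L4. Of the neuron-enriched genes 402 were higher and 754 lower, which turned to 588 and 271 when scaling and testing used these genes alone. With L4 libraries 4 to 6 alone 2691 genes were called (2276 higher and 415 lower). With L4 libraries 1 to 3 alone 6711 were called (4060 and 2651). The L4 libraries part into these sets on their leading component, which held 56.2% of their variance.

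From L4 to adult, tbh-1 rose from 208 ± 89 (n = 6) to 3108 ± 1164 (n = 7), a log2 fold change of 3.91 (SE 0.34, edgeR adjusted p = 5.38e-08). The gene tdc-1 rose by 1.74 (SE 0.25). Between L1 and adult both genes rose more in input than in neuronal IP (differences of -3.36 and -2.37), so RNA of other cells is not excluded for their rise. The let-7 microRNA gene (chromosome X, 14744104 to 14744202) fell by 6.18 (SE 0.71, from 453 ± 296 to 6.19 ± 3.32), lin-42 by 5.19 (SE 0.45) and the zinc finger gene blmp-1 by 2.30 (SE 0.25), while lin-41 rose by 2.66 (SE 0.24) to 8880 ± 3384. The cadherin genes cdh-12 and cdh-8 fell by 3.01 (SE 0.27, from 11680 ± 3474 to 1448 ± 435) and 1.89 (SE 0.19). The neuropeptide gene flp-1 fell by 1.16 (SE 0.18), and the glial gene daf-6 fell by 3.24 (SE 0.29).

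Heterochronic genes had 11 lower and 2 higher of 22 (8 and 1 of 15 with scaling on neuron-enriched genes), guanylyl cyclases 16 lower and 0 higher of 34 (10 and 0 of 33), and adhesion and guidance genes 17 lower and 3 higher of 64 (10 and 4 of 51). Chemoreceptor-type GPCRs had 84 lower and 3 higher of 785, or 9 and 2 when adjusted over the list alone. With scaling on neuron-enriched genes they had 31 lower and 5 higher of 756, and their median moved from -0.58 to -0.28. Neuropeptides had 9 higher and 8 lower of 116, and 25 higher and 2 lower of 95 with scaling on neuron-enriched genes. Germline and oocyte markers rose for 37 of 38, with the Nanos gene nos-2 at 5.11 (SE 0.60), cell division genes rose for 32 of 32, and vit-2 rose by 5.70 (SE 0.76) to 455900 ± 163400. Hypodermis and cuticle markers had 115 lower and 38 higher of 202, with bli-2 at -6.30 (SE 0.62), and sperm markers 18 lower and 3 higher of 77. The adult libraries part on these lists: libraries 1 to 3 lay below 4 to 7 in neuronal IP (sperm -4.64, hypodermis and cuticle -1.32), and the sperm list of libraries 4 to 7 was 0.01 from that of L4. In all 3674 genes were higher and 3172 lower in adults. Of the neuron-enriched genes 543 were higher and 1082 lower, which turned to 1000 and 579 when scaling and testing used these genes alone.

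**Figure D2:**
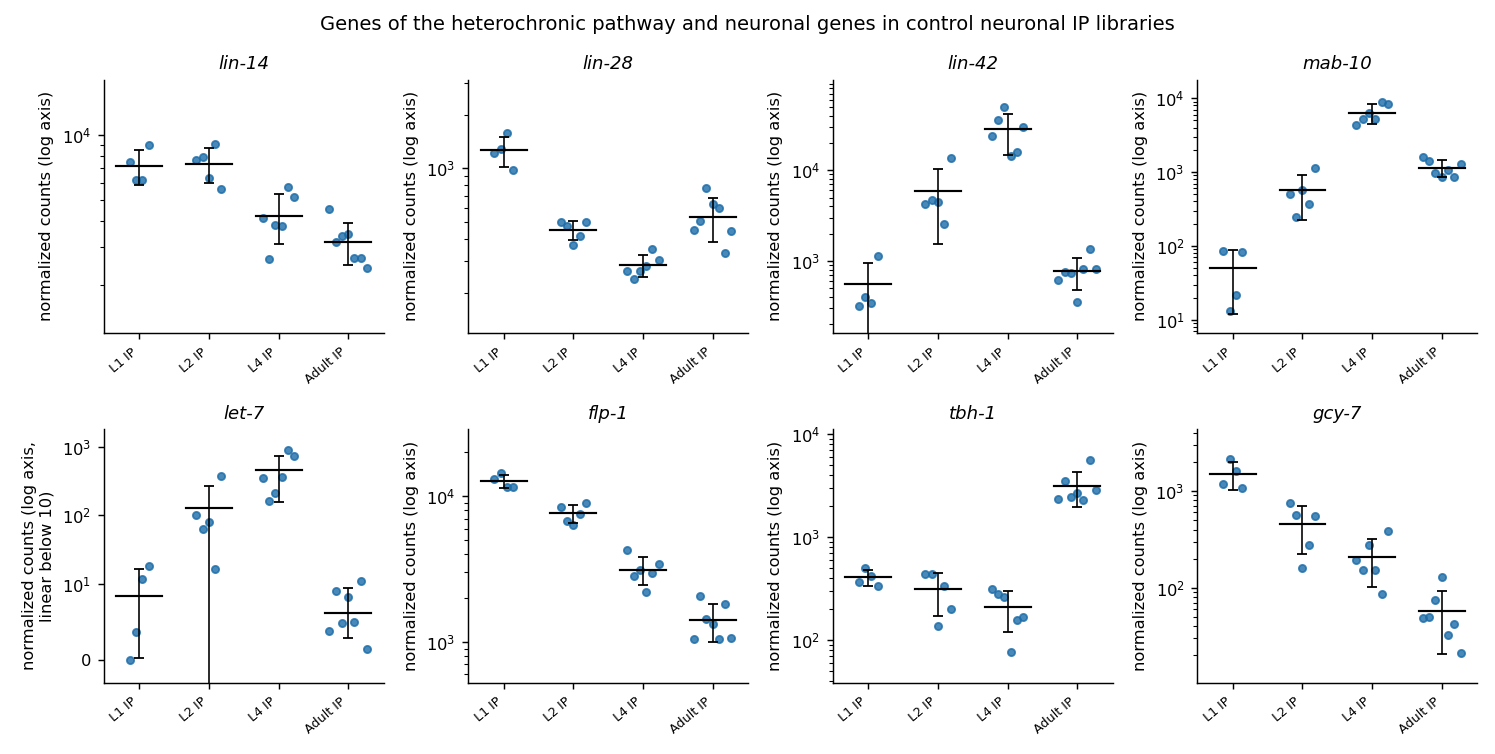
Normalized counts of 8 genes in each control neuronal IP library (points, log axis; linear below 10 for let-7), with the mean and SD by stage. From L4 to adult tbh-1 rose by 3.91 (from L1 to adult its change in neuronal IP differed from that in input by -3.36) and let-7 moved by -6.18 on the log2 scale, and gcy-7 was lower in adult than in L1 by -4.75 (-3.86 with scaling on neuron-enriched genes); the lin-14 and lin-28 calls between L1 and adult were not made with that scaling.

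From L1 to adult, the receptor guanylyl cyclase genes gcy-7 and gcy-23 fell by 4.75 (SE 0.46, from 1507 ± 495, n = 4, to 57.0 ± 36.2, n = 7; edgeR adjusted p = 3.95e-08) and 3.02 (SE 0.29), and the chemoreceptor-type genes srg-14, sri-73 and srx-56 fell by 5.41 (SE 0.56), 4.25 (SE 0.50) and 3.76 (SE 0.38). The neuropeptide gene flp-1 fell by 3.18 (SE 0.21, from 12700 ± 1317 to 1403 ± 409) and the insulin-like gene ins-30 by 2.12 (SE 0.23). The opposite was seen for mab-10, which rose by 4.53 (SE 0.50), bnc-1 (4.34, SE 0.71), zig-2 (3.85, SE 0.48), ins-9 (3.77, SE 0.50) and tbh-1 (2.94, SE 0.39). With scaling on neuron-enriched genes these 12 genes were called in the same direction, with gcy-7 at -3.86, flp-1 at -2.23 and tbh-1 at 3.94. The transcription factor gene lin-14 fell by 1.18 (SE 0.21, from 7219 ± 1348 to 3192 ± 708; adjusted p = 6.07e-05) and lin-28 by 1.24 (SE 0.19), and both calls ended with scaling on neuron-enriched genes (-0.28, adjusted p = 0.0973, and -0.31, adjusted p = 0.191).

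Guanylyl cyclases had 32 lower and 0 higher of 34 (26 and 2 of 33 with scaling on neuron-enriched genes), chemoreceptor-type GPCRs 470 lower and 15 higher of 785 (260 and 40 of 756) and ciliary transport genes 36 lower and 0 higher of 40 (29 and 2 of 40), among them dyf-19 (-2.34, SE 0.29) and bbs-8 (-1.83, SE 0.26). Adjusted over the list alone, 33, 479 and 36 genes of these lists were lower. Potassium channels had 40 lower and 8 higher of 71 (13 and 6 of 51), with kvs-5 at -2.16 (SE 0.20). Pan-neuronal genes had 8 lower and 0 higher of 22 with a median of -0.48, which turned to 10 higher and 0 lower with a median of 0.36 with scaling on neuron-enriched genes. The medians of neurotransmitter genes (-0.41), neuropeptides (-0.21), ionotropic receptors (-0.80), adhesion and guidance genes (-0.74) and heterochronic genes (-0.31) turned in the same way, to 0.49, 0.54, 0.05, 0.01 and 0.57. In the same libraries 38 of 38 germline and oocyte markers rose (median 7.04), such as the Y-box gene cey-3 (7.61, SE 0.50), and 32 of 32 cell division genes, 62 of 77 sperm markers and 16 of 25 intestine markers rose, with vit-2 at 12.06 (SE 1.2). Of these, the sperm and intestine lists differed by -4.64 and -1.28 between adult libraries 1 to 3 and 4 to 7. In all 5836 genes were higher and 5084 lower in adults; of the neuron-enriched genes 477 were higher and 4300 lower, with a median of -0.98. With scaling on neuron-enriched genes 1970 were higher and 1671 lower. That scaling takes most of these genes as unchanged and held their median between -0.09 and 0.01 in each stage comparison. The balance and the turned signs under it follow in part from this. Signs under either scaling are relative to the genes it was set on. Over the 4 stages 13102 genes differed, 4890 of them neuron-enriched, and 3764 when scaling and testing used neuron-enriched genes alone.

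**Figure D3:**
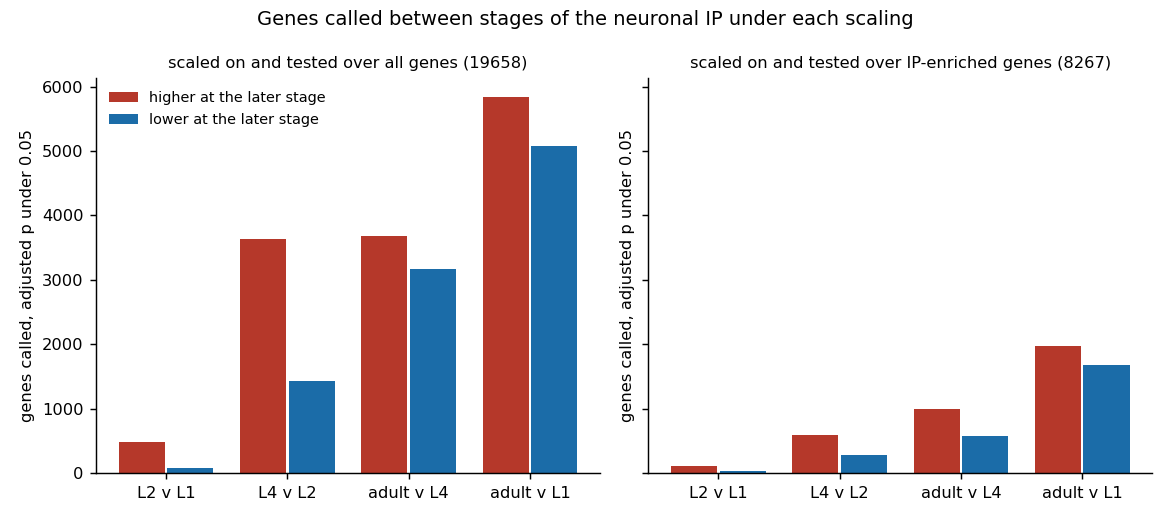
Numbers of genes called higher (red) and lower (blue) at the later stage in each comparison of neuronal IP. Scaling and testing used all 19658 genes (left) or the 8267 neuron-enriched genes alone (right). For adult against L1, 5836 were higher and 5084 lower on the left, and 1970 and 1671 on the right.

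The mutant comparisons ask whether genes that set larval timing also set neuronal expression in adults. In these 6148 genes, 1257 were higher and 1305 lower in adult than in L1 control (limma; 662 and 2548 with size-adjusted values, 609 and 2325 with the deposited values). In adults without the microRNA gene lin-4 (chromosome II, 5902231 to 5902324), let-7 was far above the adult control, at 202 ± 66.5 (n = 4) against 4.58 ± 2.74 (n = 7), a log2 fold change of 5.29 (SE 0.48, limma adjusted p = 2.1e-08). The cadherin gene cdh-12 was higher by 2.76 (SE 0.28, 7545 ± 3938 against 998 ± 133), as were the DEG/ENaC family channel gene del-3 (2.45, SE 0.38), ins-9 (2.18, SE 0.39), the transcription factor gene myrf-1 (1.67, SE 0.25) and the netrin gene unc-6 (1.11, SE 0.23). Lower were the channel genes egas-1 (-2.77, SE 0.33) and asic-2 (-1.96, SE 0.24), the neuropeptide gene nlp-14 (-1.66, SE 0.32, 1413 ± 292 against 4731 ± 2183) and the homeobox gene ceh-39 (-1.33, SE 0.30). Counts of lin-4 were listed at 0 in each of the 7 lin-4 null libraries and averaged 12.3 ± 7.60 in adult control. Transcripts of lin-14 (chromosome X, 11468435 to 11484202), the target that lin-4 represses, averaged 2730 ± 311 against 2235 ± 241 (0.29, SE 0.16, limma adjusted p = 0.291). With size-adjusted values the median of all genes in this comparison moved by 0.22, so the lin-14 difference depends on the scaling and a rise is not excluded. These are counts of nuclear RNA. Here and in the other mutant comparisons they do not measure lin-14 transcripts outside the nucleus or the protein.

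By list, 43 of 654 chemoreceptor-type GPCRs rose in the adult lin-4 null libraries, 4 fell and 607 were not called (median 0.46). Of 33 guanylyl cyclases 7 rose, 0 fell and 26 were not called, with daf-11 (0.86, SE 0.18) and odr-1 (0.90, SE 0.19) among the higher, and of 39 ciliary transport genes 5 rose, 0 fell and 34 were not called. These lists were called with the preset correlation and not with an estimated one (adjusted p = 0.351, 0.391 and 0.421). Adjusted over the list alone 40, 13 and 12 of these genes rose. Neuropeptides had 6 higher and 6 lower of 94, adhesion and guidance genes 6 and 2 of 49, and potassium channels 0 and 5 of 50. In all 258 genes were higher and 225 lower, and 1474 had an unadjusted p under 0.05. Scaling mattered for this balance: with size-adjusted values the median of all genes moved by 0.22 and 567 were higher and 109 lower, and with the deposited values 458 and 83. Without lin-4 null replicate 2 or 4 the count was 241 or 185.

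At L1 the lin-4 null differed from control in 4 genes (limma), 1 higher and 3 lower, with 186 at an unadjusted p under 0.05. The lower ones were lin-4 itself (listed at 0; 14.7 ± 12.4 in L1 control, adjusted p = 0.00278), F59G1.4, which overlaps the lin-4 gene (-1.36, SE 0.19, adjusted p = 0.000219), and F59G1.13 (-3.72, SE 0.56, adjusted p = 0.000599), and the higher one was C49G7.10 (1.27, SE 0.25, adjusted p = 0.0324); these last 3 were chosen after their values were seen, and the strand of counting is not stated. Transcripts of lin-14 averaged 2586 ± 436 (n = 3) and 2583 ± 557 (n = 4). The numbers pair these libraries, and with the replicate block 3 genes were called over all libraries and 20 in a fit of L1 libraries alone. The effect of lin-4 loss differed between adult and L1 for 54 genes (30 higher and 24 lower in adult; 123 with size-adjusted values, of which 19 lower; 77 and 15 with the deposited values), including let-7 (5.40, SE 0.76, adjusted p = 0.00015) and cdh-12 (2.59, SE 0.44, adjusted p = 0.000946), and for lin-14 the difference was 0.28 (SE 0.26, adjusted p = 0.673). With the replicate block 150 genes were called for this difference, with adult controls 1 to 3 alone 228. Without adult lin-4 null replicate 2 or 4 the count was 35 or 27, without L1 control replicate 4 it was 29, and without L1 lin-4 null replicate 2 or 3 it was 24 or 27.

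In lin-14 gain of function adults the same comparison gave let-7 at 128 ± 44.2 (n = 5), higher than control by 4.61 (SE 0.45, limma adjusted p = 5.74e-08). The channel gene del-3 was higher by 2.42 (SE 0.35), cdh-12 by 1.87 (SE 0.26, 3966 ± 1732), the long non-coding RNA gene linc-56 by 1.75 (SE 0.25) and the chemoreceptor-type gene srh-129 by 1.62 (SE 0.23). The lower genes included egas-1 (-1.73, SE 0.31), nlp-14 (-1.59, SE 0.30), ceh-39 (-1.44, SE 0.28), tdc-1 (-1.25, SE 0.28, 1132 ± 519 against 2468 ± 516) and the neuropeptide gene nlp-9 (-1.18, SE 0.21). The heat shock gene hsp-70 was lower by -2.66 (SE 0.56). Counts of lin-14 itself averaged 2096 ± 464 and differed by -0.12 (SE 0.15, limma adjusted p = 0.637). This sign turned to 0.24 with size-adjusted and 0.33 with deposited values, to 0.021 with adult controls 1 to 3 alone and to 0.019 without lin-14 replicate 2. Nuclear counts do not show whether the protein rose in this mutant.

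Chemoreceptor-type GPCRs rose for 136 of 654 and fell for 5 (median 0.53; 149 and 6 when adjusted over the list alone), guanylyl cyclases rose for 13 of 33 and fell for 2, and ciliary transport genes rose for 6 of 39 and fell for 1. The pan-neuronal genes had 0 higher and 6 lower of 22, such as the ankyrin gene unc-44 (-0.89, SE 0.16), with a median of -0.34 that turned to 0.02 with size-adjusted values. Neurotransmitter genes had 0 higher and 5 lower of 15, and ionotropic receptors 2 higher and 16 lower of 81, with a median of -0.17 that turned to 0.19. In all 541 genes were higher and 645 lower, of 2023 at an unadjusted p under 0.05. With size-adjusted values the median of all genes moved by 0.34 and 1385 were higher and 180 lower, and with the deposited values 1149 and 138. Without lin-14 replicate 2 the count was 656, and with adult controls 1 to 3 alone it was 759.

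In lin-28 gain of function adults 1 gene of 6148 was called (limma), with 575 at an unadjusted p under 0.05. It was C01F1.4, higher by 1.29 (SE 0.19, adjusted p = 0.000974), named after its value was seen. Transcripts of lin-14 averaged 2233 ± 262 (n = 3) and differed by -0.001 (SE 0.18, adjusted p = 0.999), a value that turned to 0.14 with adult controls 1 to 3 alone. Those of lin-4 averaged 4.01 ± 0.96 (adjusted p = 0.524). The lin-28 gene was not among the genes of the mutant table. Of chemoreceptor-type GPCRs 0 of 654 and of guanylyl cyclases 0 of 33 were called. With the deposited values 0 genes were called, with adult controls 1 to 3 alone 615 (392 higher and 223 lower) and with controls 4 to 7 alone 1. On the axis that parts these adult controls, the 3 lin-28 libraries lay at -0.57, -0.50 and -0.29. Controls 4 to 7 lay at -0.40 to -0.61 and controls 1 to 3 at 0.32 to 0.60. The calls against controls 1 to 3 therefore cannot be told apart from the split of the adult controls. Without adult control 6 the number of genes called was 2, and without lin-28 replicate 2 or 3 it was 0 or 3.

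Between adult lin-4 null and lin-14 gain of function libraries 11 genes differed (limma, 4 higher and 7 lower in lin-4 null; 2 and 6 with size-adjusted values and 1 and 5 with the deposited values; 344 at an unadjusted p under 0.05). One was lin-4, listed at 0 against 14.5 ± 3.88. The acetylcholine receptor-type gene acr-9 was higher by 1.03 (SE 0.22, adjusted p = 0.0269) and asic-2 lower by -1.24 (SE 0.26, adjusted p = 0.0269), and both calls were lost under some alternatives. Without lin-14 replicate 2 or lin-4 null replicate 3 or 4 the count was 7, 7 or 6.

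**Figure D4:**
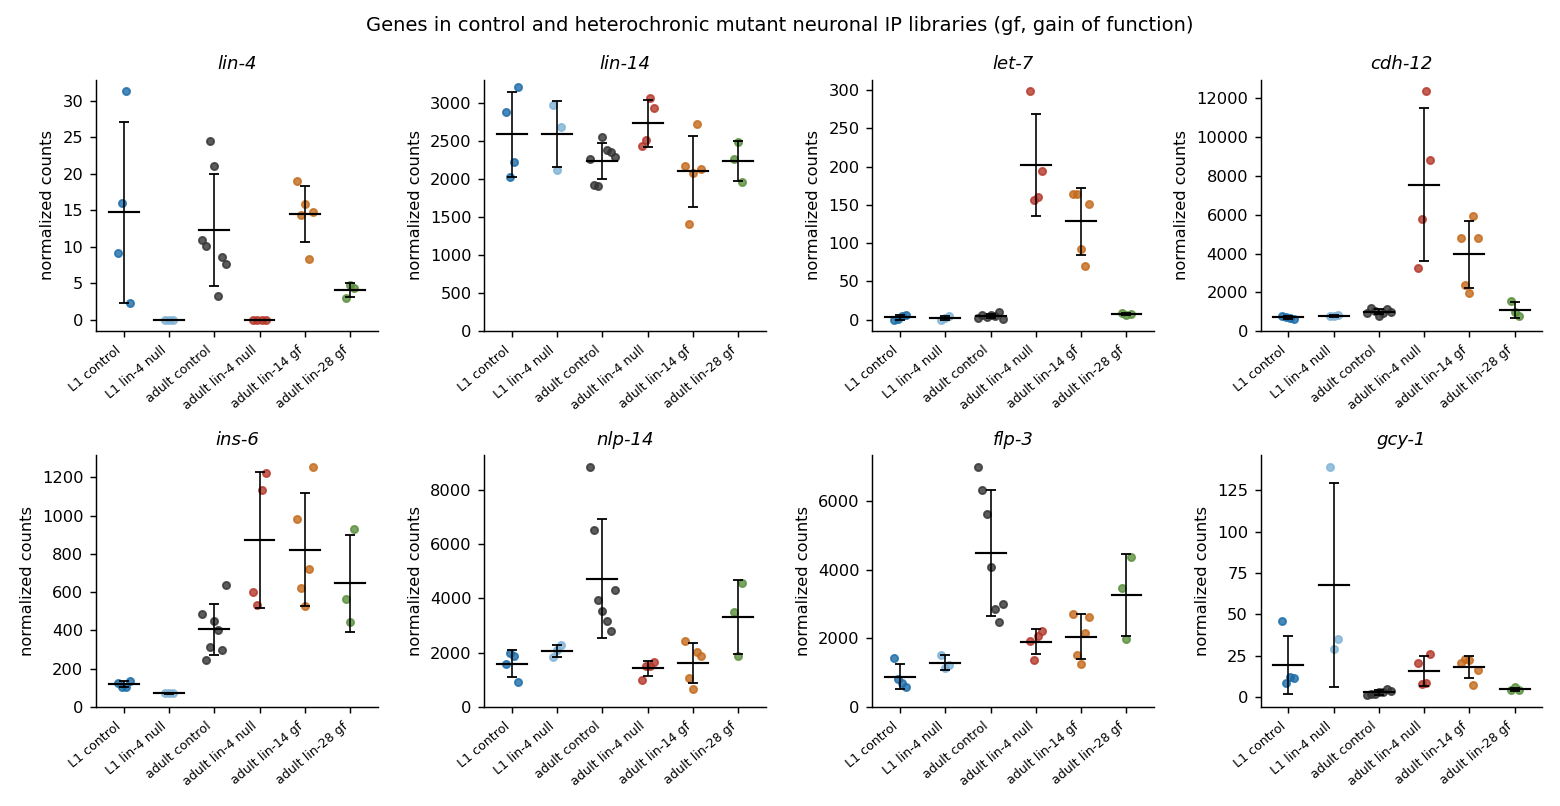
Normalized counts of 8 genes in each L1 and adult neuronal IP library of control and mutants (points), with the mean and SD. let-7 averaged 202 in adult lin-4 null, 128 in lin-14 gain of function and 4.58 in adult control, and nlp-14 averaged 1413, 1610 and 4731.

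Of the genes called in both the lin-4 null and the lin-14 gain of function adults, 365 moved in the same direction, 190 of them higher, and 0 in opposite directions. These included let-7, cdh-12, del-3, egas-1, nlp-14 and ceh-39. Independent lists of these sizes would share 46.3 genes in the same direction. With separate adult controls for each mutant 256 and 224 genes were called. The genes shared in the same direction were then fewer than 365, but more than the 4.7 of independent lists, and 0 were shared in opposite directions. The covariance of the effects was then 0.254 (0.285 with shared controls, against 0.0541 on average in simulations that share them). Of those higher in both, 116 were lower in adult than in L1 control, and of those lower in both, 147 were higher in adult.

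Of the 2562 genes that differed between adult and L1 control in this table, 311 moved in the lin-4 null in the direction opposite to development and 21 in the same direction. They were 146 genes with higher levels at L1 that rose in the mutant and 165 genes with higher levels in adults that fell. In lin-14 gain of function 763 moved in the opposite and 29 in the same direction (303 and 460 by the same division), and in lin-28 gain of function 0 and 0 (5.13% of stage genes opposite and 116 genes the same with the replicate block, and 6.28% and 55 with adult controls 1 to 3 alone). Adult controls enter both sides of these overlaps. Independent lists would give 100.8 and 246.7 opposite calls. With separate adult controls, 58 genes were opposite and 6 the same for lin-4 (19.8 opposite by independence), and 142 and 9 for lin-14 (37.8). The covariance with the stage effect was -0.227 for lin-4, -0.314 for lin-14 and 0.114 for lin-28, where simulated groups without change that share the controls averaged -0.0493, -0.0469 and -0.0540, and it was -0.202, -0.290 and 0.148 with separate controls. Without lin-4 null replicate 1, 2 or 4 the opposite calls were 180, 143 or 121, and without lin-14 replicate 2 they were 441.

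**Figure D5:**
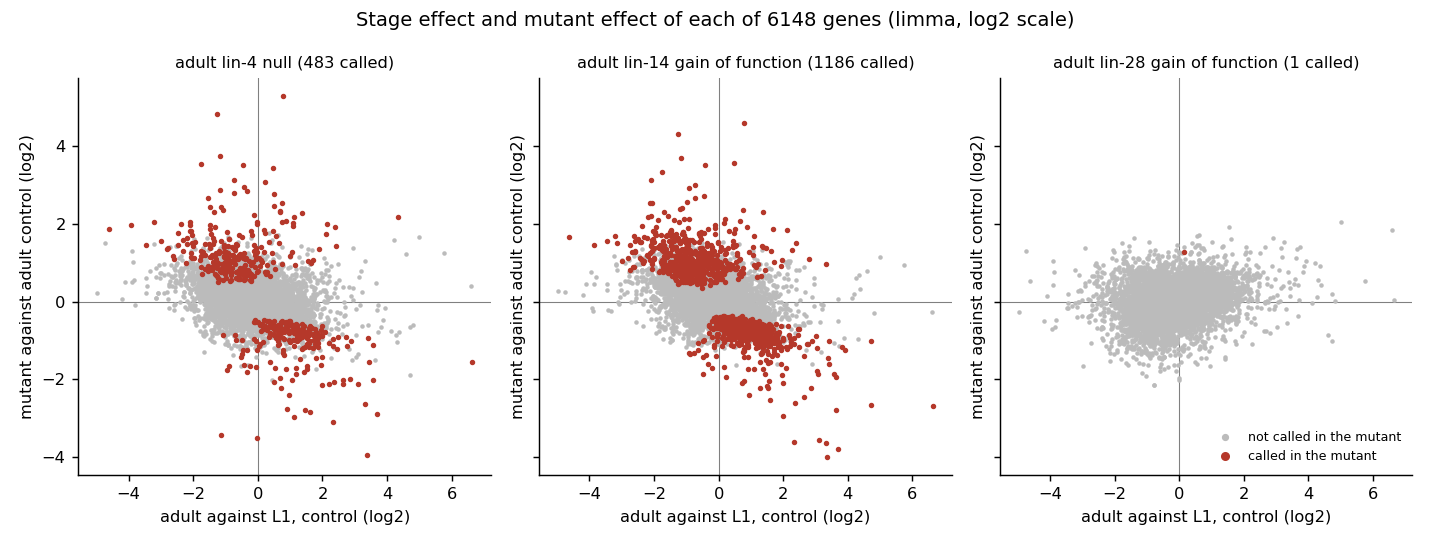
For each of 6148 genes, the log2 change from L1 to adult in control (x axis) against the log2 difference of each adult mutant from adult control (y axis), with called genes in red. Across genes, which are not independent replicates, r was -0.38 for lin-4 null, -0.49 for lin-14 and 0.24 for lin-28, and -0.35, -0.36 and -0.35 on average in simulated groups without change that share the adult controls.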

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

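The tests of the covariance with separate controls, of the subset of adult controls, of the shared preparation and of the sperm-forming stage were chosen after the results they measure were seen, as was scaling on neuron-enriched genes.

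With scaling on all genes, neuron-enriched genes were lower in adult than in L1 neuronal IP, with a median log2 fold change of -0.98. For a fall caused by few abundant genes, the median stayed at -0.98 without the 100 genes that took 22.9% of the counts. This test could hardly come out otherwise, because TMM scaling already sets aside genes of extreme abundance and fold change, so no conclusion is drawn from it. RNA of other cells in the adult pull-down is a candidate explanation: over the 4926 genes lower in neuronal IP than input, the L1 to adult change in neuronal IP and in input was correlated at r = 0.92 (Spearman 0.85; genes are not independent replicates), the germline and oocyte list moved by 6.69 and 5.85, the pharyngeal muscle list by -2.79 and -2.98, and the share of the neuronal set moved by -0.94 in neuronal IP and -0.95 in input. Other lists did not follow the input, with intestine markers at 0.92 in neuronal IP and -0.67 in input and body wall muscle markers at 0.09 and -0.66, so it does not account for every list. Gene length was not settled: over 8264 neuron-enriched genes log2 length and the change were correlated at 0.30, which is the bound set before. That rule counted only values over the bound for gene length and had no margin, but values close to it were left undecided here. A change in the neurons themselves between L1 and adult stays open as well, and was not tested apart from these.

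Adult lin-4 null and lin-14 gain of function libraries moved genes that differ between L1 and adult in the direction opposite to development. Error of single adult control libraries shared by both contrasts is argued against as the whole cause. With separate controls over 37 libraries the covariance was -0.202 for lin-4 and -0.286 for lin-14, below the lowest of 100 draws of unchanged groups (-0.0969 and -0.0830). Error common to the adult controls was not tested by this. The odd and even numbered controls each held libraries of 1 to 3 and of 4 to 7, and the draws moved libraries singly. In lin-28, with 1 gene called, the covariance with separate controls over 26 libraries was 0.148, so sizeable values also arose without many calls. Mutant animals at a stage like L4 could account for part of it, since 118 genes that peak at L4 had a median lin-4 effect of 0.79 (0.46 in lin-14, 0.20 in lin-28). Some leading genes reached L4 and not L1 levels: let-7 averaged 205 in lin-4 null, 239 at L4, 2.92 at L1 and 4.63 in adults, and cdh-12 averaged 7618, 7322, 717 and 1011. Means between adult and L4 were seen for myrf-1 (6465 in lin-4 null, 8490 at L4, 2034 in adults) and mab-10 (1937, 3666 and 831.7). Other genes highest at L4 had lin-4 null means near the adult mean. For dao-4 these were 46.18 ± 47.01 (SD) in lin-4 null, 961.9 ± 900.6 at L4 and 31.03 ± 39.62 in adults. For col-175 they were 544.9 ± 537.4, 9576 ± 10120 and 502.3 ± 811.6. These SDs are close to the means or above them, so dao-4 and col-175 weigh little here. In lin-14 gain of function both lay below the adult mean, at 5.278 and 35.29. However, 156 genes above adult level at L1 and not at L4 had 0.27 (0.35 in lin-14, -0.07 in lin-28), 66.7% of them above 0, which such a stage alone would not give. Other tissues' RNA cannot be told apart as a part of the cause, because with adult controls 1 to 3 alone, in a fit with its own stage genes, the moved genes were 394 for lin-14, against 763 with all controls, while for lin-4 they were 276 against 311 (as percents of the stage genes 24 against 29.8 and 16.8 against 12.1). With controls 4 to 7 alone no such loss was seen (893 for lin-14 and 278 for lin-4, or 31.6 and 9.83 percent). Neither can L1 expression kept by adult neurons, the explanation the design names, be told apart. Of 20 genes that move in opposite directions at L1 and L4, 25% followed L1 in lin-4 null and 40% in lin-14. Taken alone, these shares go against that explanation for these genes, since most did not follow L1 in either mutant. It was left undecided because the upper exact 95% bound was 49.1% for lin-4 null but 63.9% for lin-14. That bound takes the genes as independent, and genes measured in the same libraries are not.

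Adult control libraries 1 to 3 stood apart from 4 to 7 (the leading component of the 7 libraries held 65.1% of their variance). A difference in depth is argued against, because libraries 1 to 3 had 14467748 to 30408799 counts, within the 15592355 to 53251753 of the others except for the lowest. A difference shared by whole preparations is a candidate explanation, since over 21040 genes the difference between the sets was correlated at 0.82 between neuronal IP and input. A difference in germline content is a candidate explanation too, as the germline and oocyte list moved by 0.58 in input (0.40 in neuronal IP), above the bound of 0.5 set before; the sperm list moved by -5.01 (-4.64 in neuronal IP), so germline markers did not move alike. The size of 0.58 is not particular to germline, since in input the pan-neuronal list moved by 0.55, homeobox genes by 0.80, ribosomal proteins by -1.01 and pharyngeal muscle by -1.11. Adults of libraries 1 to 3 past a sperm-forming stage that libraries 4 to 7 still show may account for the sperm list: their sperm list median was -4.51 from that of L4 neuronal IP (-4.36 in input), and that of libraries 4 to 7 was 0.01 from it. The labels name no group that parts these sets, so no biological explanation that the design names could be tested; germline content and the sperm-forming stage are properties of the animals that it does not name.

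The change from L1 to adult differed between neuronal IP and input for 3390 genes, and the lin-4 effect differed between adult and L1 for 54 genes, each by a test of the difference itself.

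In 16 of the groups of 4 to 10 libraries taken list by list, the list median of 1 library was far from the others (log2 CPM, Dixon's test at 95%), where chance gives 1 in 20, or 8.8. In L4 input, replicate 4 had the chemoreceptor list at -2.74 (others -3.42), glia at 3.33 (2.41 to 2.56), hypodermis and cuticle at 4.30 (4.82 to 4.89), neuropeptides at 2.50 (0.92 to 1.15) and pharyngeal muscle at 5.70 (3.57 to 3.80), and replicate 3 had adhesion and guidance at 4.22 (4.58 to 4.64). In adult neuronal IP, replicate 1 had ciliary transport at 4.51 (3.40 to 3.86), homeobox genes at 3.23 (2.57 to 2.79) and potassium channels at 5.03 (4.12 to 4.41), and replicate 5 had heat shock genes at 3.53 (4.74 to 5.37). In L1 neuronal IP, replicate 1 had homeobox genes at 3.15 (3.65 to 3.67) and neuropeptides at 4.50 (5.73 to 5.92), and replicate 4 had ionotropic receptors at 4.66 (4.42 to 4.46). Hypodermis and cuticle markers were at 3.04 in L4 neuronal IP replicate 5 (4.56 to 5.22), neuropeptides at 5.94 in L2 neuronal IP replicate 1 (5.10 to 5.20) and potassium channels at 1.54 in adult input replicate 1 (1.70 to 1.75).

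Labels were also reassigned among the libraries compared. Comparisons of control libraries were fitted on their own groups, and mutant comparisons over all 26 libraries with the labels of the other groups kept. Chance can be excluded for the genes called in neuronal IP against input over all stages (1 of 50 splits gave as many; 13558, highest other split 3444), at L1 (1 of 35; 10826 and 0), L2 (1 of 56; 8809 and 3715), L4 (1 of 100; 7096 and 2530) and adult (1 of 100; 5852 and 4240). It can be excluded, with 1 of 100 splits each, for L2 against L1 (1357 and 735), L4 against L2 (4532 and 3693), adult against L4 (5974 and 89), adult against L1 (10052 and 0) and the difference of that change between neuronal IP and input (7110 and 5692), and for any stage change with 1 of 50 (13102 and 3471). These reassignments ignore the pairing of neuronal IP and input by number. Among the drawn splits that part as many pairs, the real one was highest of 8 at L1, 7 at L4 and 3 in adults, with 0 genes in each of the others, and these are too few for a share under 0.05. The comparison over all stages and the difference between neuronal IP and input were not set against such splits. Chance can also be excluded, with 1 of 100 splits each, for some mutant comparisons. These are the control stage effect (2562 and 317), lin-4 null adults (483 and 429) and lin-14 gain of function (1186 and 272). In lin-4 null adults the highest other split set adult controls 1, 2, 3 and 4 against the rest, so it follows the split of the adult libraries. With controls 1 to 3 alone 620 genes were called there and with controls 4 to 7 alone 373. Of genes moved toward L1, the real labels also gave the most, with 311 and 59 for lin-4 null and 763 and 174 for lin-14. The stage genes were kept from the real adult controls in every split. Only the real labels thus keep the error of these controls whole on both sides, so chance is not called excluded for these counts.

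Fewer calls than in some other splits were made in 4 comparisons, which points to a structure of the samples. For the adult minus L1 lin-4 effect 2 of 100 splits gave as many (54 and 200), and for lin-4 null against lin-14 gain of function 4 of 100 (11 and 525). These shares are under 0.05, but they were not corrected over the comparisons and some other splits gave far more calls. The reassignment for the adult minus L1 effect also ignored the pairing of the L1 libraries. Chance is therefore not called excluded for these calls. Nor can chance be excluded for lin-28 gain of function, where 12 of 100 splits gave as many genes (1 and 985). There the highest split set adult controls 1 to 3 against the rest. The same holds for L1 lin-4 null (2 of 35, with 4 and 61 genes). The L1 numbers pair the libraries, and of the 8 splits that part all 3 pairs the real one was highest, with 1 gene in the next. For the genes moved toward L1 by lin-28 the real count was 0, which 100 of 100 splits reach whatever the labels (highest other 333), so that count says nothing about chance.

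For the number of gene lists called with the preset correlation chance cannot be excluded in any comparison. As many lists were called by 11 of 50 splits for neuronal IP against input over all stages (16, highest other 18), 16 of 35 at L1 (16 and 19), 21 of 56 at L2 (16 and 18), 38 of 100 at L4 (17 and 19) and 39 of 100 in adults (14 and 18). Between stages these were 54 of 100 for L2 against L1 (11 and 18), 27 for L4 against L2 (16 and 18), 40 for adult against L4 (13 and 19), 38 for adult against L1 (14 and 17) and 48 for the difference between neuronal IP and input (15 and 18). In the mutants they were 47 of 100 for lin-4 null adults (4 and 9), 6 of 35 at L1 (5 and 6), 18 of 100 for the difference between these (5 and 10), 35 for lin-14 (6 and 11), 44 for lin-28 (4 and 9) and 57 for lin-4 against lin-14 (5 and 11).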

How the results depend on the processing

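Chosen after the data were examined were scaling on neuron-enriched genes, the subsets of adult and L4 libraries, the L1 fit with the block and the percent of stage genes as the measure of moved genes. Of 5207 pairs of a named gene and an alternative, 4966 kept direction and call. A further 215 kept direction and lost the call, 1 gained it and 25 turned sign, and 177 of 225 gene results never changed. The losses were mostly in L2 against L1 (71), adult lin-4 null (48) and the adult minus L1 lin-4 effect (41). The 1 gain was in adult lin-4 null libraries, where lin-14 was not called in the main comparison. All turns of sign were of uncalled values in lin-4 or lin-14: lin-14 in lin-14 gain of function (0.021 with adult controls 1 to 3, 0.33 with deposited and 0.24 with size-adjusted values, -0.22 to 0.019 without 1 library), in lin-28 gain of function (0.14 with controls 1 to 3, 0.14 with the replicate block, -0.080 to 0.090 without 1 library) and in L1 lin-4 null (-0.10 with deposited and -0.055 with size-adjusted values, -0.10 to 0.15 without 1 library), and lin-4 in the adult minus L1 effect (-0.36 with controls 1 to 3, -0.12 with the replicate block, -0.46 to 0.63 without 1 library). Where a cause is not given, the cause was not tested.

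Counts that moved by over 1.5 times were, for L2 against L1 (553), 1393 with DESeq2, 1357 with the libraries of both stages alone and 144 with scaling on neuron-enriched genes. That scaling, which tests fewer genes, gave 859 for L4 against L2, 1579 for adult against L4, 3641 for adult against L1 and 3764 for any stage change. With L4 libraries 4 to 6 alone L4 against L2 had 2691 (6711 with 1 to 3). With adult controls 1 to 3 alone there were 1640 calls for the control stage effect, 759 for lin-14, 615 for lin-28 and 228 for the adult minus L1 lin-4 effect. Of the stage genes, 12.1% were moved back in lin-4, 29.8% in lin-14 and 0% in lin-28. With adult controls 1 to 3 alone 6.28% were for lin-28, with split adult controls, and so fewer samples, 6.82% for lin-14 and 2.78% for lin-4, and with stage genes of the raw counts 13.8%, 6.67% and 0.0261% for lin-14, lin-4 and lin-28 (28.5%, 11.7% and 0% where those are scaled on neuron-enriched genes). Taken as numbers, the planned measure, the raw-count stage genes did not move lin-14 (529) or lin-4 (256) by over 1.5 times, while adult controls 1 to 3 did for lin-14 (394) and size-adjusted values for lin-4 (481). With the raw-count stage genes 141 genes moved in the same direction as development in lin-14, against 29 with the stage genes of the main comparison. Deposited values gave 0 for lin-28, 6 for lin-4 against lin-14 and 92 for the adult minus L1 effect; size-adjusted values gave 123 for that effect. Fits of the groups compared alone gave 2 for L1 lin-4 null, 7 for lin-4 against lin-14 and 98 for the adult minus L1 effect, and 7110 for the adult against L1 difference between neuronal IP and input (3390 over all control libraries). A pseudocount of 0.5 gave 2 for lin-28 and of 10 gave 2 for L1 lin-4 null. Estimated correlations left 0 lists in each of the 16 comparisons, and with neuron-enriched genes alone 8 lists were called for L4 against L2, 8 for adult against L4 and 7 for adult against L1.

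The replicate block gave 12011 for adult neuronal IP against input, 6167 for its difference from L1, 20 for L1 lin-4 null in the fit of L1 libraries alone and 150 for the adult minus L1 effect. It moved no other count by over 1.5 times where numbers pair samples: 15038 for neuronal IP against input over all stages, 12996 at L1, 7811 at L4 and 3 for L1 lin-4 null over all libraries. Where samples share only a number, the block gave 12288 for L2 neuronal IP against input, 268 for L2 against L1, 4788 for L4 against L2, 5737 for adult against L4, 9026 for adult against L1, 11441 for any stage change, 2026 for the control stage effect, 708 for lin-4 null adults, 996 for lin-14, 660 for lin-28, 15 for lin-4 against lin-14, and moved genes of 18.1%, 28.3% and 5.13% for lin-4, lin-14 and lin-28.

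Leaving out 1 library gave 13325 to 15010 calls for neuronal IP against input over all stages, 9653 to 10363 at L1, 7300 to 9436 at L2, 8242 to 9911 at L4, 6726 to 10898 in adults and 2427 to 4146 for the difference between L1 and adult. Between stages it gave 155 to 667 for L2 against L1, 4173 to 5706 for L4 against L2, 6095 to 7274 for adult against L4, 9584 to 11186 for adult against L1 and 12256 to 13277 for any change. For the mutants it gave 2138 to 2687 for the control stage effect, 185 to 526 for lin-4 null adults, 3 to 5 at L1, 24 to 81 for the adult minus L1 effect, 656 to 1227 for lin-14, 0 to 3 for lin-28, 6 to 10 for lin-4 against lin-14, and moved genes of 4.82% to 13.5%, 16.7% to 33.2% and 0% to 0% for lin-4, lin-14 and lin-28. In simulations at these depths and group sizes, changes of 2-fold were called for 12.3% of 65 changed genes between L1 and L2 and 20.3% of 74 between L1 and adult. In adults they were called for 58.9% of 73 genes in lin-4 null and 73.4% of 64 in lin-14. Few of the genes run (19223 and 19218 for the stages, 6148 for the mutants) were changed. This makes the adjusted p stricter than in a comparison with many calls, so these shares do not measure the sensitivity of such comparisons.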

Other observations

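The gene lin-41 was lower at L4 than at L2 and in adults in neuronal IP, with 7955 ± 1843 normalized counts (SD, n = 5) at L2, 1404 ± 192 (n = 6) at L4 and 8880 ± 3384 (n = 7) in adults, while lin-42 stood at 5938 ± 4410, 28280 ± 13390 and 776 ± 299 in the same libraries. Neither gene was neuron-enriched, and which cells these levels come from was not tested. The cadherin gene cdh-12, at 11680 ± 3474 at L4 and 1448 ± 435 in adults, was among the genes higher in both adult lin-4 null and lin-14 gain of function libraries.

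The label field for the genotype of the lin-28 gain of function names an allele of lin-14 while the protocol names alleles of lin-14 and lin-28, so the group was taken from the sample titles.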
